A study of Mus musculus with 18 samples.

How the data were processed

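RNA was measured in regulatory T cells (Treg), CD4+ cells that express the transcription factor Foxp3 and restrain other immune cells. The cells were enriched on a CD4 column and sorted on the yellow fluorescent protein (YFP) that the Foxp3-YFP-cre allele produces, from male mice aged 6 to 8 weeks. Per the labels, 18 libraries fall into 6 groups of 3: wild type (Foxp3-YFP-cre alone) and floxed Dyrk1, HDAC1, HDAC2, Mef2c or Mef2d alleles deleted by the same cre. The series text calls the 3 replicates of each group independent and biological. Libraries were made with NEBNext Ultra II and sequenced as paired reads on Illumina instruments. The labels name the mm10 genome build, STAR and HTSeq, without versions, strand setting or annotation release. Raw reads were not analysed here.

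The values deposited by the authors were treated as FPKM (fragments scaled by gene length and depth). Neither the labels nor the table names the unit, and it was read from the values themselves. RPKM and FPKM cannot be told apart from the values, and FPKM was chosen because the reads were paired. Totals ranged from 430017 to 493453 FPKM per library. Multiplying each value by gene length and by a factor per library returned whole reads, within 0.03 of an integer, for 100% of the 23799 gene identifiers above 0. The table holds no gene lengths, so they were fitted. The annotated exon union was used where it gave whole reads, and otherwise the smallest length that did. That share was therefore partly fixed by the fit, most of all for genes read in few libraries. The recovered depth was 15.9 to 24.1 M reads per library, and intervals on it would cover counting error only. Of 35275 Ensembl identifiers, 34490 had a symbol and 785 had none. The fitted gene length equalled the exon union of the GENCODE M21 annotation held here for 6779 identifiers, so the annotation release is not known. Chromosome positions are from that annotation on mm10.

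Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 12223 genes. A single fit with a mean per group over all 18 libraries had 12 residual degrees of freedom, with a trend of variance on level. Each of the 5 deletion groups was compared with wild type, HDAC1 with HDAC2, and Mef2c with Mef2d, and an F test covered all 6 groups. Adjusted p-values are Benjamini-Hochberg values from limma over all genes tested, with 0.05 as the threshold and no minimum fold. Because counts were not available, 3 parts of a plan written for counts took the form stated in it for normalised values. Library scaling was left as the authors made it, the alternative scaling was a median of ratios (RLE) computed from the values, and the minimum level for naming a gene was 5 FPKM. Folds are log2 differences of log2(FPKM + 1) with the standard error (SE) of the fit, and group values are mean FPKM ± SD (n = 3).

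Choices made before the data were examined were the comparisons, the tests, 34 gene lists, the rule for naming genes and most alternatives. The adapted parts named above, among them the minimum of 5 FPKM for naming, were set after the unit had been read. Genes were named by 3 rules. The first took the targeted genes and Rcor1, which the growth protocol describes as knocked out. The second took the 10 largest rises and 10 largest falls (5 each way for the direct comparisons of deletion groups) among genes that passed, reached 5 FPKM in the higher group and had all 3 libraries of a group beyond all 3 of the other. Clone-like symbols, immunoglobulin and T cell receptor segments and Y-linked genes were left out of that rule. The third took up to 4 members of each list that passed, or up to 2 as values alone where none passed. Lists with at least 5 tested members, 31 in number, were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone. Some genes that the rules select are not reported here. For comparisons with wild type, lists not described in the text are shown with their result in the figure of gene lists.

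Overlap between deletion groups was set against the product expectation and against 100 simulations of unchanged groups that share the wild-type libraries. The fit was tested on simulated data, in which 50 genes per fold were changed in a single comparison. They were drawn from genes averaging over 100 reads per library, so recovery of more weakly read genes was not tested. At 1.25-fold 22% were recovered, at 1.5-fold 66%, at 2-fold 92% and at 4-fold 96%. Unchanged genes made up 6.67% of those calls, and 0 genes passed in a comparison left unchanged. A shifted cell cycle list passed camera at an adjusted p of 1.79e-09, with 0 other lists called. Each gene was simulated independently, whereas the estimated correlation of that list in the data was 0.803. The simulation therefore does not test list calls among genes that move together.

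The alternatives set beforehand were a pseudocount of 0.1, no filter on low values, RLE scaling, the replicate number as a block, a minimum absolute log2 fold of 1, a fit of the compared groups alone, an estimated camera correlation, and each library left out in turn. Added after seeing the data were limma voom on the recovered reads, omission of the 3 libraries highest in B cell markers (Dyrk1, Mef2c and Mef2d replicate 1), a B cell marker covariate, and removal of each library's trend on gene length and GC content. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Permutation tests were exact and two-sided. With 3 libraries against 3 the smallest p they allow is 0.1.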

Results

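Gene expression was measured by RNA sequencing in sorted Foxp3+ YFP+ regulatory T cells from 6 groups of 3 male mice. Recovered depth was 18.54 to 20.62 M reads in wild type, 18.41 to 21.77 in Dyrk1, 18.26 to 21.28 in HDAC1, 21.64 to 24.09 in HDAC2, 18.27 to 20.64 in Mef2c and 15.92 to 22.55 in Mef2d libraries. Foxp3, the transcription factor that defines Treg, was read at 82.5 to 117.7 FPKM in the 18 libraries. The series asks what each Foxp3-cre deletion does to Treg RNA.

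The targeted genes were examined first in every library. Hdac1, a class I histone deacetylase (ENSMUSG00000028800, chromosome 4, 129516104 to 129542713), was at 32.0 ± 4.34 FPKM in libraries labelled HDAC1 deletion and 119 ± 3.05 in wild type, a log2 change of -1.87 (SE 0.07, adjusted p 9.54e-10). In the other 4 deletion groups Hdac1 averaged 107 to 123.5 FPKM. Its paralog Hdac2 (ENSMUSG00000019777, chromosome 10, 36974544 to 37001889) was at 27.9 ± 0.937 FPKM in libraries labelled HDAC2 deletion and 28.3 ± 0.519 in wild type, which did not pass (log2 -0.02, SE 0.05, adjusted p 0.795). The MEF2 transcription factor gene Mef2d (ENSMUSG00000001419, chromosome 3, 88142372 to 88172086) was higher, not lower, in libraries labelled Mef2d deletion, at 53.4 ± 0.561 against 41.7 ± 4.59 FPKM (log2 0.35, SE 0.08, adjusted p 0.00718). That call was lost after removal of length and GC trends, at a log2 change of 0.24. Mef2c (ENSMUSG00000005583, chromosome 13, 83504034 to 83667080) was near the detection floor of the test, at 1.27 ± 0.594 FPKM in libraries labelled Mef2c deletion and 0.476 ± 0.151 in wild type (log2 0.59, SE 0.51, adjusted p 0.446), with 8.02 FPKM in Dyrk1 replicate 1.

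The label Dyrk1 does not say which of 2 kinase genes was floxed. Dyrk1a (ENSMUSG00000022897, chromosome 16, 94570010 to 94695517) was at 33.1 ± 2.58 FPKM in libraries labelled Dyrk1 deletion and 27.7 ± 1.46 in wild type (log2 0.25, SE 0.08, adjusted p 0.0352). The Dyrk1a call was lost with RLE scaling, with no filter, without the 3 libraries rich in B cell markers, after removal of length and GC trends, in a fit of the 6 libraries alone, and in a fit without any 1 wild-type library (log2 0.27, 0.27 and 0.21) or Dyrk1 replicate 3 (log2 0.19). Dyrk1b (ENSMUSG00000002409, chromosome 7, 28179469 to 28187294) rose to 11.8 ± 0.789 from 7.001 ± 0.466 FPKM (log2 0.68, SE 0.10, adjusted p 0.000679). So 1 of the 5 labels was met by a lower level of its gene that passed. Rcor1, a corepressor gene that the growth protocol describes as knocked out although no label carries it, averaged 15.8 FPKM in wild type and 17.6 to 19.0 in the 5 deletion groups. The lowest group means of Hdac2 (26.2 FPKM) and Mef2d (37.9 FPKM) were in Dyrk1-labelled libraries. Calls against the other 4 deletion labels within 20 Mb of Hdac2 had an odds ratio of 3.61 with the HDAC2 label and 0.893 with the Dyrk1 label, and near Mef2d of 2.36 with the Mef2d label and 1.26 with the Dyrk1 label (Fisher exact p 1.65e-05, 0.721, 4.55e-05 and 0.0981). Windows elsewhere reached as high a share in 0.202% of cases for Hdac2 but 7.89% for Mef2d, which left Mef2d undecided. The HDAC1 label also had an odds ratio of 1.9 near Mef2d (Fisher exact p 0.0045). Away from Mef2d 22.4% of genes were called with the Dyrk1 label and 5.25% with the Mef2d label, so their odds ratios are not alike. The FPKM values cover whole genes, including exons that are not floxed, and do not by themselves check a deletion. Groups are therefore named by label in every comparison that follows, and each direction is that of the labelled libraries.

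**Figure D1:**
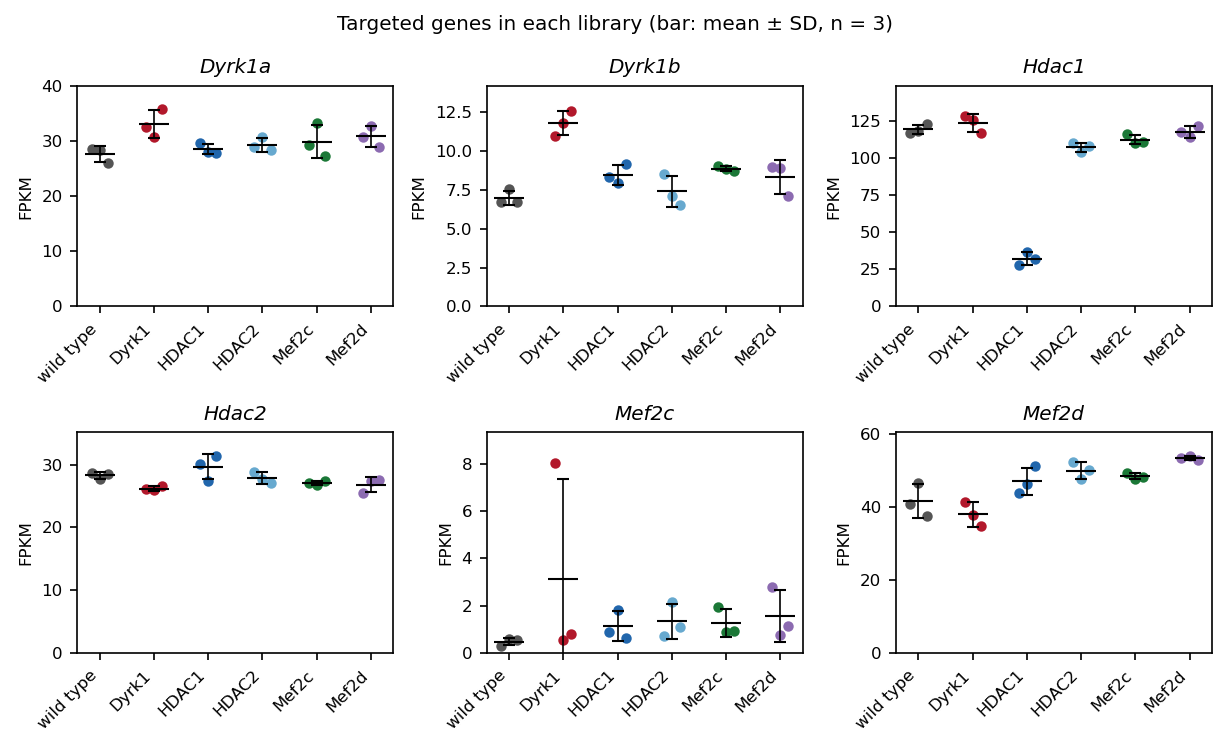
FPKM of the 6 targeted genes (y axes) in each of the 18 libraries (points), with mean ± SD per group (bars, n = 3). Hdac1 sits at 32.0 FPKM in the HDAC1 group and 119 in wild type, while Hdac2 (27.9 against 28.3 FPKM) did not pass in its group, and Mef2c, Mef2d, Dyrk1a and Dyrk1b are not lower in the groups that carry their names.

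Libraries labelled Dyrk1 deletion carried more RNA of p53 targets and cell cycle inhibitors. Sesn2, a stress-induced regulator of mTORC1, rose from 3.60 ± 0.0534 to 15.5 ± 2.80 FPKM (log2 1.83, SE 0.12, adjusted p 4.36e-07). Bbc3, which encodes the BH3-only protein PUMA, rose from 21.2 ± 1.28 to 60.5 ± 6.73 FPKM (log2 1.47, SE 0.10). The CDK4/6 inhibitor gene Cdkn2c rose from 10.7 ± 2.09 to 22.5 ± 1.39 FPKM (log2 1.03, SE 0.14). Of 17 tested members of the list of cell cycle inhibitors and p53 targets, 9 rose, 1 fell and 7 did not pass (10 up and 1 down adjusted over the list alone). Camera gave an adjusted p of 9.07e-05, and 0.0170 with an estimated correlation, the only list call in the 5 comparisons with wild type that held with that estimate.

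Genes of resting T cells were lower in the Dyrk1-labelled libraries. The surface protein gene Ly6c1 fell from 97.3 ± 16.4 to 21.5 ± 7.94 FPKM (log2 -2.19, SE 0.25, adjusted p 0.000129), and Igfbp4, a carrier of insulin-like growth factors, fell from 115 ± 14.4 to 52.9 ± 5.89 FPKM (log2 -1.10, SE 0.15). Of 16 list members 8 fell and 0 rose by limma (9 down adjusted over the list alone; camera adjusted p 1.00e-06, adjusted p = 0.417 with an estimated correlation). Cell cycle genes were higher, with 9 of 34 risen and 0 fallen (15 up adjusted over the list alone; camera adjusted p 6.58e-07, adjusted p = 0.648 with an estimated correlation). The proliferation marker Mki67 rose from 19.5 ± 5.45 to 45.5 ± 7.66 FPKM (log2 1.20, SE 0.19). That cell cycle count was 4 without wild-type replicate 2 or Dyrk1 replicate 3, 5 without wild-type replicate 1 or Dyrk1 replicate 1 or 2, and 19 without wild-type replicate 3. Without the 3 libraries rich in B cell markers it was 4.

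Some targets of NFAT and NF-kB, which carry T cell receptor signals, also rose in the Dyrk1-labelled libraries, with 7 of 17 up and 0 down (7 up and 1 down adjusted over the list alone; camera adjusted p 0.0222, adjusted p = 0.491 with an estimated correlation). Cd83, a membrane protein of activated lymphocytes, rose from 32.6 ± 1.77 to 55.1 ± 2.27 FPKM (log2 0.74, SE 0.08). Without the 3 libraries rich in B cell markers this list missed the threshold (adjusted p 0.0760). Among other genes, the meiotic cohesin gene Rec8 (log2 1.84, SE 0.17), the PI3-kinase regulatory subunit gene Pik3r3 (log2 1.66, SE 0.14) and the antiproliferative gene Btg2 (log2 1.11, SE 0.11) rose. The glutathione transferase gene Gsta4 fell from 26.8 ± 0.945 to 4.46 ± 1.21 FPKM (log2 -2.37, SE 0.21), the myosin gene Myo6 fell (log2 -1.76, SE 0.14), and the Treg-associated receptor gene Gpr83 fell from 36.5 ± 1.68 to 17.1 ± 2.85 FPKM (log2 -1.06, SE 0.13). The Treg identity list had 4 members up, 3 down and 13 that did not pass (5 up and 4 down adjusted over the list alone; camera adjusted p 0.688).

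By limma, 2116 of 12223 genes passed in the Dyrk1-labelled libraries, 1359 higher and 757 lower. With RLE scaling the split was 1091 higher and 920 lower, and after removal of length and GC trends 654 and 833. The count was 1247 without wild-type replicate 3 and 1186 without Dyrk1 replicate 3. In a fit of these 6 libraries alone 58 genes passed, and the call on Mki67, unlike those on Sesn2, Bbc3, Cdkn2c, Ly6c1, Igfbp4 and Cd83, was lost. Dyrk1 replicate 1 had a mean log2(FPKM + 1) of 5.705 over B cell genes and 22.4 FPKM of Cd8a, against 3.039 to 3.073 and 0.642 to 0.939 in the other 2 libraries of the group. Erythroid genes were lower as a list (median log2 -1.95; camera adjusted p 0.00408, adjusted p = 0.558 with an estimated correlation), with 1 of 6 called (5 down adjusted over the list alone). That count was 0 without Dyrk1 replicate 1 or 2 or wild-type replicate 2 or 3, 2 without Dyrk1 replicate 3 and 5 without wild-type replicate 1. Hba-a1 was at 2.50 to 16.8 FPKM, against 12.9 to 164 in wild type.

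Libraries labelled HDAC1 deletion showed their largest falls in genes close to Hdac1. Ncmap, a myelin protein gene, fell from 12.6 ± 0.764 to 1.23 ± 0.208 FPKM (log2 -2.61, SE 0.12, adjusted p 2.39e-09). Sfn, which encodes the 14-3-3 sigma protein, fell from 29.86 ± 0.9504 to 8.63 ± 0.713 FPKM (log2 -1.68, SE 0.07), and the nucleosome-binding protein gene Hmgn2 fell from 106 ± 16.9 to 36.4 ± 2.31 FPKM (log2 -1.51, SE 0.12). Wdtc1 rose from 15.9 ± 0.145 to 34.3 ± 0.768 FPKM (log2 1.06, SE 0.05). All 4 lie within 20 Mb of Hdac1 on chromosome 4. Away from it, the H3K4 methyltransferase genes Kmt2a (log2 1.11, SE 0.19) and Kmt2c (log2 1.06, SE 0.16) and the lysosomal trafficking gene Lyst (log2 1.12, SE 0.19) rose.

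Il4, a Th2 cytokine gene, rose in the HDAC1-labelled libraries from 1.29 ± 0.155 to 3.57 ± 0.413 FPKM (log2 0.99, SE 0.19, adjusted p 0.00613). The checkpoint receptor gene Havcr2 (TIM-3) rose from 2.39 ± 0.341 to 4.67 ± 0.832 FPKM (log2 0.74, SE 0.12). Itga4, an integrin subunit gene of lymphocyte trafficking, rose from 34.0 ± 6.11 to 53.2 ± 4.87 FPKM (log2 0.64, SE 0.13). The Th2 list as a whole did not pass, with 1 of 7 up and 0 down (2 up adjusted over the list alone; camera direction down, adjusted p 0.985), a median log2 of -0.07 and a mean of 0.15. Of 15 Th1 genes 4 rose and 0 fell (6 up adjusted over the list alone; camera adjusted p 0.0153, adjusted p = 0.713 with an estimated correlation). That Th1 count was 1 without HDAC1 replicate 1 or 2 or wild-type replicate 3, and 2 without wild-type replicate 1 or 2. Markers of gamma-delta T and NKT cells were higher too, with 2 of 7 up and 0 down (3 up adjusted over the list alone; median log2 0.68; camera adjusted p 0.0310, adjusted p = 0.713 with an estimated correlation), 0 without HDAC1 replicate 1 or 2 or wild-type replicate 3 and 1 without wild-type replicate 1. Among class I HDACs and their complexes 4 of 26 rose and 1, Hdac1 itself, fell (4 up and 1 down adjusted over the list alone; camera adjusted p 0.919).

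Plasma cell genes were higher in the HDAC1-labelled libraries, with 3 of 7 up and 0 down (7 up adjusted over the list alone; camera adjusted p 0.00768, adjusted p = 0.713 with an estimated correlation). Igha, the constant region of IgA, was at 2656 ± 1802 FPKM and 629 ± 443 in wild type (log2 2.10, SE 0.54, adjusted p 0.0217). That call was lost without wild-type replicate 1 (log2 1.94) or 3 (log2 1.72) or HDAC1 replicate 2 (log2 1.58), and the list count was then 0 in each case. Igha was also lost in a fit of these 6 libraries alone. Cell cycle genes shifted down as a list (median log2 -0.24; camera adjusted p 1.54e-05, adjusted p = 0.718 with an estimated correlation), although limma called 0 of 34 members over all genes and 0 adjusted over the list alone. Without wild-type replicate 2 limma called 15 lower.

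In all, 1533 genes passed limma in the HDAC1-labelled libraries, 1250 higher and 283 lower. With RLE scaling the split was 763 higher and 717 lower, and after removal of length and GC trends 445 and 566, which turns its direction. The count was 421 without wild-type replicate 3, 923 without wild-type replicate 1, 512 without HDAC1 replicate 1, 805 without replicate 2 and 1016 without replicate 3. It was 932 in a fit of these 6 libraries alone.

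Libraries labelled HDAC2 deletion had lower levels of nearly the whole cell cycle list, although Hdac2 itself was unchanged by the test. Of 34 cell cycle genes 32 fell, 0 rose and 2 did not pass (34 down adjusted over the list alone; median log2 -0.84; camera adjusted p 4.49e-22, adjusted p = 0.401 with an estimated correlation). Ccna2, cyclin A2 of S and G2 phase, fell from 20.6 ± 6.84 to 8.40 ± 1.81 FPKM (log2 -1.17, SE 0.19, adjusted p 0.00251). The replicative helicase gene Mcm7 fell from 57.0 ± 9.95 to 34.9 ± 2.06 FPKM (log2 -0.68, SE 0.11), Tyms, thymidylate synthase, from 8.95 ± 1.97 to 4.74 ± 0.263 FPKM (log2 -0.78, SE 0.14), and the mitotic ubiquitin conjugase gene Ube2c from 22.4 ± 8.55 to 8.13 ± 1.17 FPKM (log2 -1.30, SE 0.24). With any 1 of the 6 libraries left out, 24 to 34 cell cycle genes still fell.

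Energy metabolism genes were lower as well in the HDAC2-labelled libraries. Of 33 nuclear oxidative phosphorylation genes 19 fell and 0 rose (23 down adjusted over the list alone; camera adjusted p 6.25e-13, adjusted p = 0.401 with an estimated correlation), among them the ATP synthase subunit gene Atp5a1, from 276 ± 19.7 to 211 ± 4.27 FPKM (log2 -0.38, SE 0.07). The count was 9 without wild-type replicate 3, 11 without HDAC2 replicate 1 and 10 without HDAC2 replicate 2. Of 18 glycolysis genes 9 fell and 2 rose (10 down and 3 up adjusted over the list alone; camera adjusted p 0.00161, adjusted p = 0.612 with an estimated correlation). Tpi1, triosephosphate isomerase, fell from 85.1 ± 20.8 to 48.3 ± 4.11 FPKM (log2 -0.78, SE 0.14) and the enolase gene Eno1 from 373 ± 28.7 to 274 ± 4.98 FPKM (log2 -0.44, SE 0.07). The 2 that rose were Pdk1, a kinase that inhibits pyruvate dehydrogenase, and the glucose transporter gene Slc2a3, from 13.2 ± 0.0847 to 19.8 ± 0.600 FPKM (log2 0.55, SE 0.08).

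Some effector Treg genes fell and some Th1 genes rose in the HDAC2-labelled libraries. The effector list had 5 of 28 members down and 0 up (3 down adjusted over the list alone; camera adjusted p 0.0257, adjusted p = 0.682 with an estimated correlation), and 3 down with any of the 6 libraries left out, with 1 up without HDAC2 replicate 1 or 3. Lgals1, the lectin galectin-1, fell from 260 ± 40.9 to 139 ± 9.66 FPKM (log2 -0.89, SE 0.15), the chemokine receptor gene Ccr8 from 36.0 ± 4.33 to 21.3 ± 2.52 FPKM (log2 -0.73, SE 0.15) and the costimulatory receptor gene Icos from 86.8 ± 8.54 to 59.9 ± 2.88 FPKM (log2 -0.52, SE 0.11). Of 15 Th1 genes 6 rose and 0 fell (8 up adjusted over the list alone; camera adjusted p 0.0125, adjusted p = 0.612 with an estimated correlation), and 3 rose without wild-type replicate 2 or HDAC2 replicate 2. Tbx21, which encodes T-bet, the master regulator of Th1 cells, rose from 4.17 ± 1.01 to 10.4 ± 3.21 FPKM (log2 1.12, SE 0.26, adjusted p 0.00706), and the death ligand gene Fasl from 2.68 ± 0.514 to 5.93 ± 1.08 FPKM (log2 0.91, SE 0.15). CD8 T and NK cell genes moved with them, with 4 of 13 up and 0 down (4 up adjusted over the list alone; camera adjusted p 0.142), among them the perforin gene Prf1 (log2 0.90, SE 0.22) and Klrb1c (log2 1.23, SE 0.28). HDAC2 replicate 2 was the highest of its group on both lists, at a mean log2(FPKM + 1) of 3.717 and 2.766.

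Plasma cell genes were higher in the HDAC2-labelled libraries too, with 6 of 7 up and 0 down (6 up adjusted over the list alone; camera adjusted p 0.00336, adjusted p = 0.612 with an estimated correlation). Igha was at 4820 ± 3231 FPKM (log2 2.96, SE 0.54, adjusted p 0.00291), and Tnfrsf17, which encodes the plasma cell receptor BCMA, rose from 1.08 ± 0.350 to 3.38 ± 0.821 FPKM (log2 1.07, SE 0.22). The count was 2 without wild-type replicate 3 or HDAC2 replicate 2 and 3 without wild-type replicate 1. Among other genes, Acads, a mitochondrial acyl-CoA dehydrogenase gene, fell from 21.8 ± 0.0857 to 2.30 ± 0.202 FPKM (log2 -2.79, SE 0.08, adjusted p 2.22e-11). The dendritic cell and T cell transcription factor gene Batf3 (log2 -1.55, SE 0.30) and the chemokine gene Ccl22 (log2 -1.40, SE 0.27) fell. Zfp683, which encodes the tissue-residency factor Hobit, rose from 2.08 ± 0.033 to 13.0 ± 5.55 FPKM (log2 2.11, SE 0.36), and the drug efflux pump gene Abcb1a (log2 1.37, SE 0.24) and Kmt2a (log2 1.23, SE 0.19) rose.

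The HDAC2-labelled libraries differed from wild type at 3123 genes by limma, 1973 higher and 1150 lower. With RLE scaling 1412 were higher and 1630 lower, and after removal of length and GC trends 1154 and 1474, so the balance of directions turned under both. The count was 1329 without wild-type replicate 3 and 1742 without HDAC2 replicate 1.

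**Figure D2:**
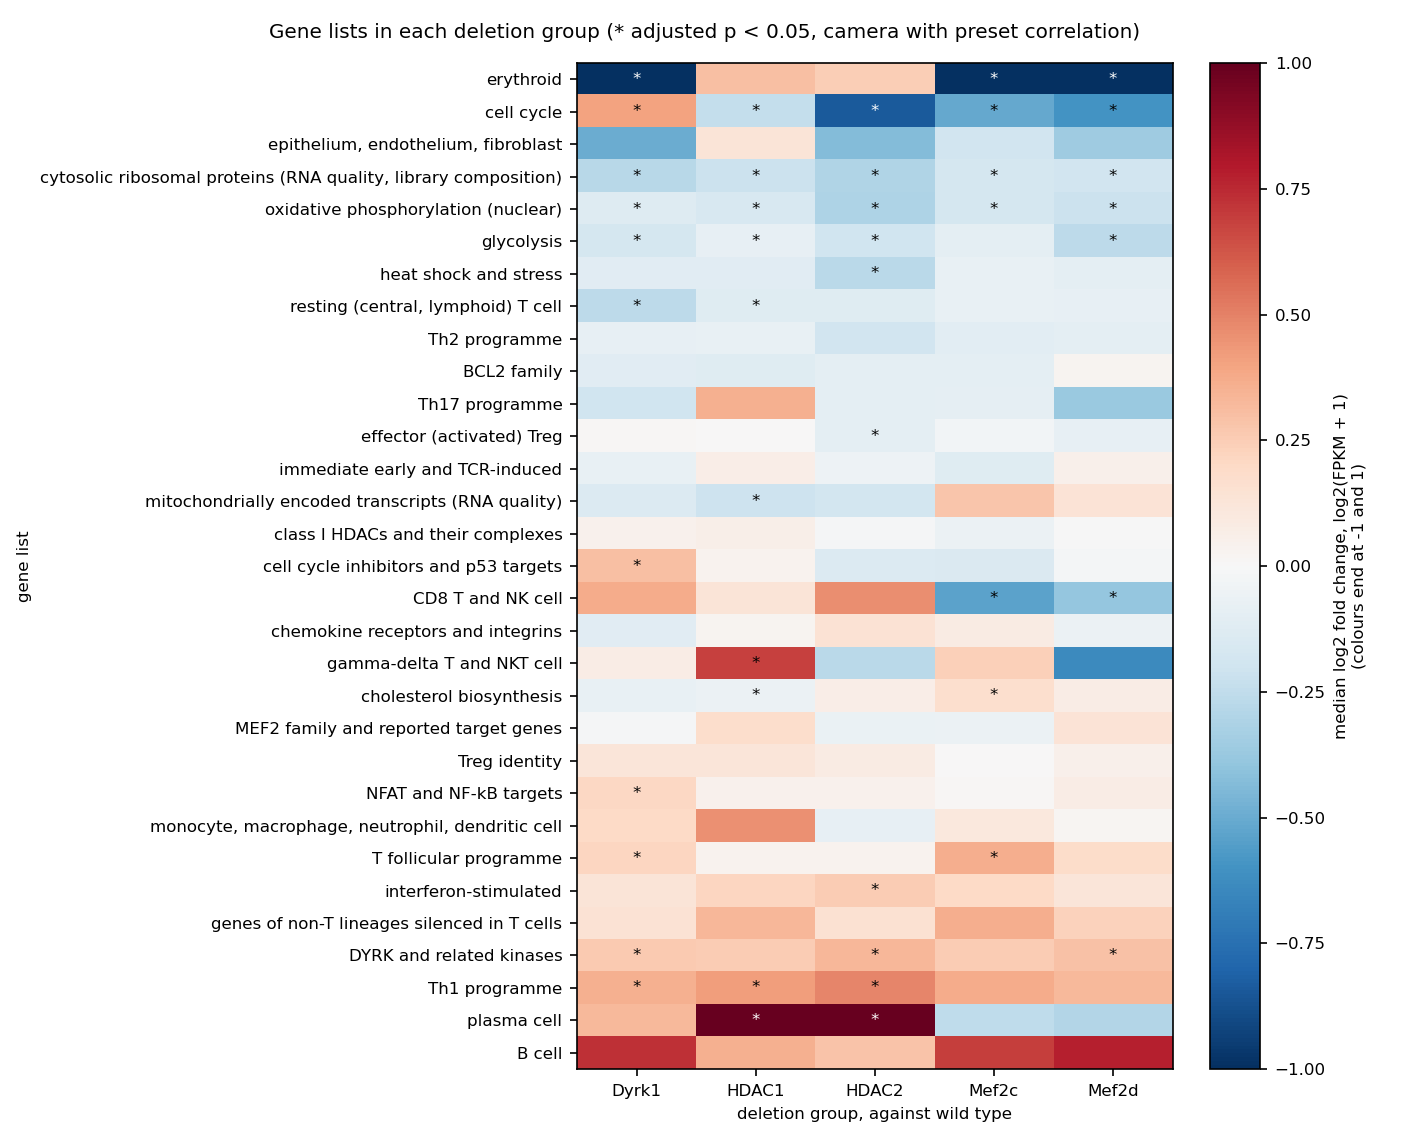
Median log2 fold change of log2(FPKM + 1) (colour, ending at -1 and 1) for each gene list (y axis) in each deletion group against wild type (x axis), with stars where camera at a preset correlation gave an adjusted p under 0.05. The cell cycle list is at -0.84 in the HDAC2 group and at 0.40 in the Dyrk1 group.

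Libraries labelled Mef2c deletion had strongly lower Lrrc32, which encodes GARP, the receptor that holds latent TGF-beta on Treg, at 17.7 ± 1.52 against 73.4 ± 7.20 FPKM (log2 -1.99, SE 0.17, adjusted p 1.30e-06). The antiviral restriction factor genes Trim12a and Trim5 fell, with Trim12a at 0.0268 ± 0.0357 against 23.63 ± 1.251 FPKM (log2 -4.58, SE 0.51) and Trim5 at 0.0641 ± 0.0364 against 12.8 ± 1.24 (log2 -3.69, SE 0.37). Slfn8, a Schlafen family gene, fell from 25.6 ± 3.74 to 2.22 ± 0.674 FPKM (log2 -3.06, SE 0.14). The phosphatase-family gene Mtmr9 rose from 12.5 ± 2.40 to 102 ± 4.59 FPKM (log2 2.95, SE 0.11), the acute-phase gene Orm2 from 2.51 ± 0.167 to 28.2 ± 1.21 FPKM (log2 3.06, SE 0.13), and the interferon-induced gene Xaf1 from 14.2 ± 3.74 to 50.9 ± 1.57 FPKM (log2 1.80, SE 0.17).

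Some cholesterol synthesis and follicular T cell genes rose in the Mef2c-labelled libraries. Of 19 cholesterol genes 6 rose and 0 fell (6 up and 1 down adjusted over the list alone; camera adjusted p 0.0172, adjusted p = 0.585 with an estimated correlation). Stard4, a cholesterol carrier, rose from 9.05 ± 0.598 to 19.9 ± 2.24 FPKM (log2 1.05, SE 0.10). Of 11 follicular genes 6 rose and 0 fell (7 up adjusted over the list alone; camera adjusted p 0.0383, adjusted p = 0.585 with an estimated correlation), including Cxcr5, the homing receptor for B cell follicles, from 10.9 ± 0.268 to 19.2 ± 1.91 FPKM (log2 0.76, SE 0.15). Il18r1, a receptor subunit for IL-18, rose from 20.7 ± 1.51 to 48.1 ± 4.37 FPKM (log2 1.18, SE 0.12), while the quiescence factor gene Klf2 fell from 239 ± 14.9 to 154 ± 14.5 FPKM (log2 -0.63, SE 0.14). In the list of the MEF2 family and reported targets 2 of 15 rose and 2 fell (4 up and 2 down adjusted over the list alone; camera adjusted p 0.503). Those that rose included Hdac9, a class IIa deacetylase that binds MEF2 (log2 0.76, SE 0.18).

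Cell cycle genes were lower in the Mef2c-labelled libraries, with 17 of 34 down and 0 up (28 down adjusted over the list alone; median log2 -0.52; camera adjusted p 6.67e-13, adjusted p = 0.585 with an estimated correlation). Mcm2, a helicase subunit, fell from 47.1 ± 7.88 to 32.1 ± 2.83 FPKM (log2 -0.53, SE 0.11). The count was 1 without wild-type replicate 3, 7 without wild-type replicate 1, 32 without wild-type replicate 2, 2 without Mef2c replicate 1 and 4 without Mef2c replicate 2. Without the 3 libraries rich in B cell markers it was 1. Among 13 CD8 T and NK cell genes 2, the NK receptor genes Klrb1c (log2 -1.51, SE 0.28) and Klra8 (log2 -0.83, SE 0.17), fell and 0 rose (2 down adjusted over the list alone; camera adjusted p 0.0478, adjusted p = 0.761 with an estimated correlation), a list call lost with RLE scaling (adjusted p 0.103), with voom (adjusted p 0.0521) and after removal of length and GC trends (adjusted p 0.108).

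For the Mef2c label, limma called 2322 genes, 1581 higher and 741 lower. RLE scaling gave 1073 higher and 1104 lower, and removal of length and GC trends 1008 and 1127, which turned the balance. The count was 1150 without wild-type replicate 3, 1160 without Mef2c replicate 1, 1307 without the 3 libraries rich in B cell markers and 1341 in a fit of these 6 libraries alone. Over B cell genes the mean log2(FPKM + 1) was 4.316 in Mef2c replicate 1 and 3.45 and 3.812 in the others, against 2.762 to 3.407 in wild type. The haemoglobin gene Hba-a1 was at 6.45 to 21.9 FPKM, against 12.9 to 164 in wild type.

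Libraries labelled Mef2d deletion shared several of these changes. Lrrc32 fell from 73.4 ± 7.20 to 36.5 ± 11.4 FPKM (log2 -1.02, SE 0.17, adjusted p 0.00108) and Trim12a from 23.63 ± 1.251 to 2.19 ± 3.79 (log2 -3.65, SE 0.51). Orm2 rose from 2.51 ± 0.167 to 34.3 ± 4.88 FPKM (log2 3.32, SE 0.13), Il18r1 from 20.7 ± 1.51 to 49.1 ± 3.71 (log2 1.21, SE 0.12) and Pstpip2, an adaptor that restrains inflammation in myeloid cells, from 2.22 ± 0.815 to 19.9 ± 0.871 (log2 2.72, SE 0.22). Ccr4, a chemokine receptor for skin homing, fell from 23.6 ± 4.68 to 8.66 ± 1.03 FPKM (log2 -1.34, SE 0.13), and Batf3 fell (log2 -1.73, SE 0.30). Btla, an inhibitory receptor, rose from 34.7 ± 2.29 to 54.2 ± 2.58 FPKM (log2 0.63, SE 0.06).

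Cell cycle genes were lower in the Mef2d-labelled libraries as well, with 21 of 34 down and 0 up (30 down adjusted over the list alone; median log2 -0.60; camera adjusted p 7.03e-13, adjusted p = 0.739 with an estimated correlation). Mcm7 fell from 57.0 ± 9.95 to 38.5 ± 2.31 FPKM (log2 -0.54, SE 0.11). The count was 2 without wild-type replicate 3, 6 without wild-type replicate 1, 32 without wild-type replicate 2, 4 without Mef2d replicate 1 and 7 without Mef2d replicate 2. Without the 3 libraries rich in B cell markers it was 2. Of 18 glycolysis genes 9 fell and 3 rose (9 down and 3 up adjusted over the list alone; camera adjusted p 0.00841, adjusted p = 0.739 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 433 ± 60.6 to 325 ± 7.04 FPKM (log2 -0.40, SE 0.09), while Slc2a3, Pfkp and Pdk1 rose. Without wild-type replicate 3 or Mef2d replicate 1 glycolysis genes that fell numbered 5, and without Mef2d replicate 1 or 2 those that rose numbered 1.

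The Mef2d-labelled libraries also had lower RNA of 3 NK receptor genes. Of 13 CD8 T and NK cell genes 3 fell and 0 rose (4 down and 1 up adjusted over the list alone; camera adjusted p 0.0297, adjusted p = 0.739 with an estimated correlation), a list call lost with RLE scaling (adjusted p 0.0939), voom (adjusted p 0.0599) and removal of length and GC trends (adjusted p 0.0934). Klrb1c fell (log2 -1.57, SE 0.28), as did the NK receptor genes Klrc1 (log2 -1.32, SE 0.32) and Klra8 (log2 -0.78, SE 0.17). Tcrg-C1, a gamma chain constant region, fell from 28.8 ± 8.99 to 12.3 ± 1.59 FPKM (log2 -1.12, SE 0.22), while its list, gamma-delta and NKT cells, did not pass (3 of 7 down, 0 up, 4 down adjusted over the list alone; camera adjusted p 0.0633). DYRK and related kinases had 4 of 10 members up and 0 down (4 up adjusted over the list alone; camera adjusted p 0.0297, adjusted p = 0.739 with an estimated correlation), among them Dyrk2 (log2 0.45, SE 0.09) and Hipk1 (log2 0.51, SE 0.09). That kinase count was 2 without wild-type replicate 3 or Mef2d replicate 1 or 2, and the list call was lost after removal of length and GC trends (adjusted p 0.0934). The Dyrk1 label also had 4 of 10 up and 0 down on this list (camera adjusted p 0.0222, 0.491 with an estimated correlation). Its count was 1 without wild-type replicate 3 or Dyrk1 replicate 3. Without the 3 libraries rich in B cell markers its list call was lost (camera adjusted p 0.0567). With the HDAC2 label 4 rose and 0 fell.

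Mef2d-labelled and wild-type libraries differed at 2677 genes by limma, 1705 higher and 972 lower. RLE scaling gave 1222 higher and 1346 lower, and removal of length and GC trends 946 and 1114, again the opposite balance. The count was 1079 without wild-type replicate 3, 1353 without Mef2d replicate 1, 1637 without Mef2d replicate 2 and 1467 without the 3 libraries rich in B cell markers. Over B cell genes the mean log2(FPKM + 1) was 4.731 in Mef2d replicate 1 and 3.08 and 3.695 in the others. Hba-a1 was at 5.12 to 24.9 FPKM.

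**Figure D3:**
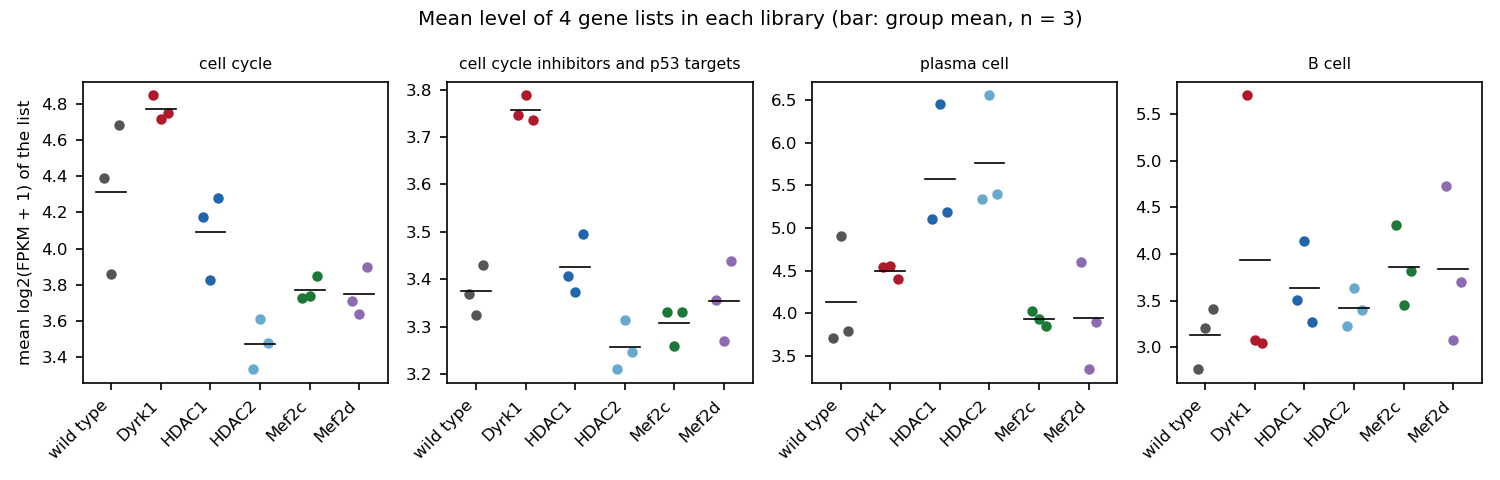
Mean log2(FPKM + 1) over the members of 4 gene lists (y axes) in each library (points), with the mean of each group (bars, n = 3). Wild-type libraries spread widely on the cell cycle list, and Dyrk1, Mef2c and Mef2d replicate 1 are the highest of their groups on the B cell list.

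HDAC1 and HDAC2 are paralogs found in the same corepressor complexes, so their labelled groups were compared directly. Havcr2 was at 4.67 ± 0.832 FPKM in HDAC1-labelled and 2.00 ± 0.281 in HDAC2-labelled libraries (log2 0.92, SE 0.12, adjusted p 0.000550). Acads (log2 2.77, SE 0.08), the cytidine deaminase family gene Apobec2 (log2 1.51, SE 0.13) and the matrix protease gene Mmp14 (log2 1.26, SE 0.14) were higher with the HDAC1 label. Ncmap (log2 -2.78, SE 0.12), Sfn (log2 -1.74, SE 0.07) and Hdac1 (log2 -1.72, SE 0.07) were lower. Cell cycle genes were higher with the HDAC1 label as a list (median log2 0.68; camera adjusted p 1.40e-24, adjusted p = 0.229 with an estimated correlation), with 2 of 34 called over all genes and 34 adjusted over the list alone. Those 2 calls were lost on leaving out any HDAC2 library or HDAC1 replicate 1 or 3, and 10 were called without HDAC1 replicate 2. Effector Treg, Th17 and gamma-delta and NKT lists were also higher with the HDAC1 label (camera adjusted p 0.00220, 0.000284 and 0.000191; adjusted p = 0.476, 0.229 and 0.229 with an estimated correlation), with 2 of 28, 1 of 7 and 0 of 7 called (2, 5 and 5 up adjusted over the list alone). Cholesterol and CD8 T and NK cell lists were lower (camera adjusted p 1.44e-05 and 0.0118; adjusted p = 0.229 and 0.640 with an estimated correlation), with 1 of 19 and 1 of 13 called (3 and 2 down adjusted over the list alone). Apart from HDAC1 replicate 2, leaving out any of the 6 libraries left 1 effector Treg and 0 Th17 and CD8 and NK calls, and the cholesterol call stayed only without HDAC2 replicate 2. Oxidative phosphorylation, stress, glycolysis and ribosomal protein lists were higher too by camera (adjusted p 8.10e-05, 0.00939, 0.0182 and 0.0437). With an estimated correlation camera gave adjusted p = 0.640, 0.229, 0.658 and 0.828. Limma called 0 of 33, 0 of 16, 2 of 18 and 0 of 30 members. The glycolysis count was 0 without HDAC1 replicate 1 or 3 or HDAC2 replicate 1 or 3, and 1 without HDAC2 replicate 2. Same-numbered libraries of these labels correlated (r 0.21, 0.428 and 0.132), a pairing that these tests left out. Limma called 183 genes in this comparison, 129 higher and 54 lower, and after removal of length and GC trends 124 and 84. The count was 57 without HDAC1 replicate 1, 54 without HDAC1 replicate 3, 64, 96 and 74 without HDAC2 replicate 1, 2 or 3, and 96 in a fit of the 6 libraries alone.

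MEF2C and MEF2D are transcription factors of 1 family, and their labelled groups were also compared directly. Mtmr9 (102 ± 4.59 against 13.7 ± 0.0248 FPKM; log2 2.81, SE 0.11), the XK-related membrane protein gene Xkr6 (log2 2.54, SE 0.15), the interferon-induced gene Ifi44l (log2 2.93, SE 0.12), Xaf1 (log2 1.66, SE 0.17) and Stard4 (log2 0.83, SE 0.10) were higher with the Mef2c label. Slfn8 (2.22 ± 0.674 against 39.8 ± 4.06 FPKM; log2 -3.68, SE 0.14), the synaptic adaptor gene Tspoap1 (log2 -2.61, SE 0.23), the extracellular matrix gene Ecm1 (log2 -0.66, SE 0.09) and Btla (log2 -0.36, SE 0.06) were lower. With the Mef2c label Lrrc32 was lower than with the other (log2 -0.97, SE 0.17, adjusted p 0.00302), a call lost in a fit of these 6 libraries alone. Cholesterol genes were higher with the Mef2c label as a list, with 1 of 19 called (1 up adjusted over the list alone; camera adjusted p 0.00225, adjusted p = 0.535 with an estimated correlation), and the list missed the threshold without the 3 libraries rich in B cell markers (adjusted p 0.0964). Markers of gamma-delta T and NKT cells had the stronger call, with 2 of 7 higher and 0 lower (4 up adjusted over the list alone; median log2 0.86; camera adjusted p 0.000931, adjusted p = 0.535 with an estimated correlation), 0 without Mef2d replicate 2 and 1 without any other of the 6 libraries. Limma called 374 genes, 196 higher and 178 lower. That balance turned without Mef2c replicate 1 (133 and 190), without the 3 libraries rich in B cell markers (130 and 162), with the replicate block (165 and 172) and after removal of length and GC trends (189 and 197). The count was 240 without Mef2d replicate 2 or Mef2c replicate 3, 243 without Mef2c replicate 2, and 246 in a fit of these 6 libraries alone.

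The 5 deletion labels were then compared through their shared control. HDAC1-labelled and HDAC2-labelled libraries had 941 genes higher in both and 167 lower in both, with 6 in opposite directions, where independence would give 202, 26.6 and 163. Mef2c-labelled and Mef2d-labelled libraries had 997 higher and 439 lower in both, with 13 opposite, where independence would give 221, 58.9 and 229. Across genes, which are not independent replicates, log2 changes correlated at r 0.760 and 0.766 in these pairs, and at 0.233 to 0.493 in the other 8. Simulated unchanged groups that share the 3 wild-type libraries gave mean r of 0.494 and 0.477 for the related pairs, with highest values of 0.913 and 0.893 above those measured, and mean r of 0.463 to 0.549 for the other 8 pairs, each above its measured r. Covariances were 0.107 and 0.133, against simulated means of 0.0215 and 0.0203 and highest values of 0.0872 and 0.0859. Genes called in the same direction numbered 1108 for the HDAC pair, 690 without wild-type replicate 1 and 269 without wild-type replicate 3. They numbered 1436 for the MEF2 pair and 517 without wild-type replicate 3. The other 8 pairs had 656 to 1714, the most for HDAC2 with Mef2d, so wide sharing was not particular to the related pairs. Every pair exceeded independence, which groups that share wild-type libraries do not meet. In the simulations such genes numbered at most 0 for the HDAC pair and 2 for the MEF2 pair, but 791 for HDAC2 with Mef2c (mean 9.16). The simulated groups held no changed genes, so these counts are not matched to the data. Same-numbered libraries also correlated within the HDAC pair (r 0.132 to 0.428) and the MEF2 pair (r 0.31 to 0.396). The controls are too few to be divided between the comparisons.

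Cytosolic ribosomal protein genes fell against wild type under all 5 labels, with 12 of 30 down for Dyrk1, 5 for HDAC1, 18 for HDAC2, 7 for Mef2c and 8 for Mef2d, and 0 up in each (23, 13, 25, 8 and 13 down adjusted over the list alone). Camera gave adjusted p-values of 6.19e-11, 5.63e-12, 6.25e-13, 8.32e-08 and 4.07e-07, and adjusted p = 0.558, 0.713, 0.401, 0.585 and 0.739 with an estimated correlation. Without wild-type replicate 3 the counts were 5, 0, 6, 3 and 1. They were 7, 1, 2 and 1 for Dyrk1, HDAC1, Mef2c and Mef2d without wild-type replicate 1. Leaving out a deletion library gave 6 without Dyrk1 replicate 3, 1 without HDAC1 replicate 1 or 2, 3 without HDAC1 replicate 3, 10 without HDAC2 replicate 2, 2 and 4 without Mef2c replicate 1 or 2, and 1, 3 and 5 without Mef2d replicate 1, 2 or 3.

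Among 33 nuclear oxidative phosphorylation genes 19 fell for HDAC2, 7 for Mef2d and 6 for HDAC1, but only 2 for Mef2c and 1 for Dyrk1 (23, 10, 6, 0 and 0 down adjusted over the list alone). For HDAC2, Mef2d, HDAC1, Mef2c and Dyrk1 camera gave adjusted p-values of 6.25e-13, 4.07e-07, 3.51e-08, 1.42e-05 and 0.000861, all lost with an estimated correlation (adjusted p = 0.401, 0.739, 0.713, 0.585 and 0.747). After removal of length and GC trends the Dyrk1 call was lost (adjusted p 0.149). Mitochondrially encoded transcripts, a list for RNA quality, were lower as a list with the HDAC1 label (median log2 -0.20), although limma called 0 of 12. Camera gave an adjusted p of 0.00724, and 0.718 with an estimated correlation, a list call lost after the same removal (adjusted p 0.0703). Without wild-type replicate 3 the oxidative phosphorylation counts were 9, 3, 0, 0 and 0 for HDAC2, Mef2d, HDAC1, Mef2c and Dyrk1. They were 3 for HDAC1 and 1 for Mef2c without wild-type replicate 1, and 4 for Mef2c without wild-type replicate 2. Without a deletion library they were 2, 0 and 0 for Dyrk1 replicates 1, 2 and 3, 0, 1 and 2 for HDAC1, 0, 0 and 5 for Mef2c, 11 and 10 for HDAC2 replicates 1 and 2, and 4 and 4 for Mef2d replicates 1 and 2. Over the 6 groups together, 4721 genes passed the F test, 558 of them with an absolute log2 change of at least 1.

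**Figure D4:**
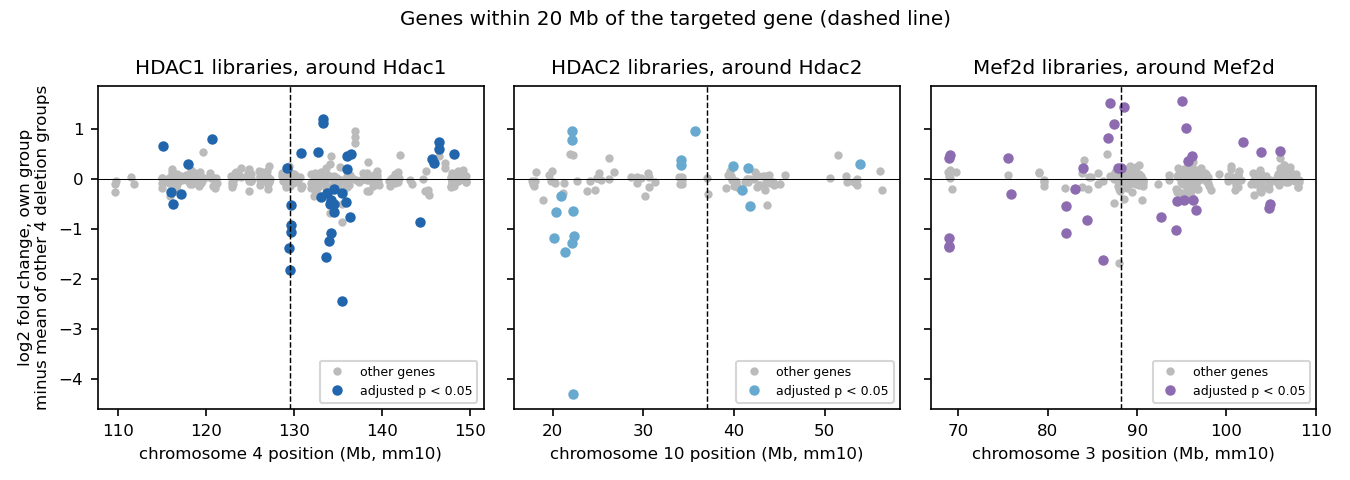
Log2 fold change of each tested gene within 20 Mb of Hdac1, Hdac2 and Mef2d (dashed lines), own label minus the mean of the other 4 deletion labels (y axis), by chromosome position in Mb on mm10 (x axis), with coloured points at an adjusted p under 0.05. Called genes near Hdac1 number 38 of 344, near Hdac2 18 of 102 and near Mef2d 33 of 285.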

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

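The tests of loci, of wild-type libraries and of immunoglobulin reads in this part were chosen only after the results were seen. The HDAC1 and HDAC2 labels and the Mef2c and Mef2d labels are singled out here because they differ from each other directly. HDAC1-labelled libraries differed from HDAC2-labelled ones at 183 genes by limma, although the proteins share complexes. The largest rises were Hmgb1-ps8 (log2 4.38), the acyl-CoA dehydrogenase gene Acads (2.77), Apobec2 (1.51), the secretion gene Baiap3 (1.29) and Mmp14 (1.26). The largest falls were Atp6v0c-ps2 (-4.55), Ncmap (-2.78), Sfn (-1.74), Zfp683 (-1.72) and Hdac1 (-1.72). Hmgb1-ps8 and Atp6v0c-ps2 are pseudogenes whose reads can come from their parent genes, so these values are uncertain. Zfp683 lost its call without HDAC1 replicate 1 (-1.62) or 3 (-1.49) or HDAC2 replicate 1 (-1.80) or 2 (-1.42), and Baiap3 without HDAC1 replicate 1 (1.37), 2 (1.22) or 3 (1.29).

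Mef2c-labelled libraries differed from Mef2d-labelled ones at 374 genes. The largest rises were Eif3s6-ps2 (log2 4.69), the interferon-induced gene Ifi44l (2.93), Mtmr9 (2.81), the chromatin protein gene Hmga1b (2.57) and Xkr6 (2.54). The largest falls were Rps3a3 (-8.09), Rps3a2 (-5.13), Slfn8 (-3.68), the histone gene Hist1h2al (-2.98), listed at 0 in all 3 Mef2c libraries, and Tspoap1 (-2.61). Eif3s6-ps2, Rps3a2, Rps3a3 and Hmga1b have near-identical relatives and their values are uncertain.

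Calls concentrated near some targeted genes, which could come from DNA of another mouse strain carried with the floxed allele or from loss of the protein. Each label was set against the other 4 deletion labels within 20 Mb. In HDAC2-labelled libraries 18 of 102 genes near Hdac2 were called against 5.61% elsewhere (odds ratio 3.61, Fisher exact p 1.65e-05). That share was reached by 0.202% of 494 windows elsewhere, and the odds ratio's lower limit of 2.03 argues against an even spread of calls. Another 654 of 11662 genes away from Hdac2 were called, so effects of the missing protein across the genome are not excluded. For HDAC1 (38 of 344; odds ratio 2.29, lower limit 1.57; 5.04% of 496 windows as high) and Mef2d (33 of 285; odds ratio 2.36, lower limit 1.58; 7.89% of windows) the windows, added after the Fisher result, left it undecided, and HDAC1-labelled libraries also had 27 of 285 calls near Mef2d (odds ratio 1.90, p 0.00450). Mef2c (odds ratio 1.54, p 0.0976) and Dyrk1a (odds ratio 0.664, p 0.245) were undecided too. Whether DNA of another strain lies at other genes, such as Lrrc32, Trim12a and Trim5, was not tested.

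Wild-type libraries stood apart from all 5 deletion labels, which might reflect length or GC trends, chance values of 3 shared controls, or a separate preparation. In all 5 comparisons 309 genes were higher and 25 lower, together 334 against a highest of 0 in 100 simulations. The simulated groups held no changed genes, so the adjustment let few genes pass in most simulations. Many genes passed in the data, which eases the threshold, so the simulations could not decide on chance values of the controls. After removal of length and GC trends 133 genes met the same rule, 68 higher and 65 lower, not all of them among the 334. The simulations were not repeated after that removal, so 133 has no matching chance count. Such trends as the whole cause stayed undecided. The count was 52 without wild-type replicate 3, RLE scaling gave 141 higher and 88 lower, and the transcript Gm42418, at the ribosomal RNA locus and singled out after its values were seen, was at 2008 to 3024 FPKM in wild type and 339 to 1351 in the 15 deletion libraries. Wild type differed from the rest at 3242 genes, against 577 to 2365 for the other groups, but the labels give no date or batch, and a separate preparation could not be decided.

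Immunoglobulin reads were higher in the HDAC1-labelled (log2 1.55, SE 0.683) and HDAC2-labelled (log2 1.95, SE 0.658) libraries, which may come from B cells or from plasma cells or their free RNA, although CD4 enrichment and sorting on YFP select against both. A first test, the rise of other B cell reads (log2 0.72, SE 0.372, and 0.41, SE 0.278), gave no decision. It was replaced, after the values were seen, by immunoglobulin reads per B cell read, which exceeded Mef2c-labelled libraries by a log2 of 3.21 (SE 0.428) in HDAC2-labelled and 2.50 (SE 0.418) in HDAC1-labelled ones, but wild-type libraries by only 1.54 (SE 0.552) and 0.83 (SE 0.544), so that B cells stay open as a source. Plasma cell reads without immunoglobulin were higher by 2.16 (SE 0.713) and 1.60 (SE 0.677) in the HDAC2 and HDAC1 labels, consistent with plasma cells, at an exact permutation p of 0.1, the smallest possible.

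Other splits of the libraries were fitted the same way. For each 3 against 3 comparison the true split was 1 of 10, too few for a share under 0.05. The true counts for Dyrk1, HDAC1, HDAC2, Mef2c and Mef2d against wild type were 2116, 1533, 3123, 2322 and 2677, and the highest other split gave 1, 1, 1, 0 and 0 genes. The direct comparisons had 183 and 374, each with a highest other of 1. For the 6 groups the true grouping, with 4721 genes, was 1 of 100, and the highest other had 25.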

How the results depend on the processing

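The settings voom, B cell covariate, omission of the 3 B-rich libraries, and length and GC removal were tests chosen only after results were seen. No named gene and no called list reversed, although lists without a call did change direction and list tests were not rerun with 1 library left out. The balance of higher and lower genes turned with RLE for HDAC2, Mef2c and Mef2d, with length and GC removal for all 5 labels, for Dyrk1 in its 2 groups alone (26 and 32), and for Mef2c against Mef2d with RLE, the replicate block, length and GC removal, without the 3 B-rich libraries and without Mef2c replicate 1 or 3; the cause was not tested. Of the values of named genes 5335 kept their side of the threshold, 610 were weaker and 70 stronger; with 1 library left out 3201 kept it, 775 were weaker and 16 stronger. With a minimum absolute log2 fold of 1 counts were 77, 121, 221, 232 and 194 for Dyrk1, HDAC1, HDAC2, Mef2c and Mef2d, 39 for HDAC1 against HDAC2, 94 for Mef2c against Mef2d and 558 over 6 groups, because the setting itself removes small changes. In fits of the compared groups alone, which hold fewer samples, they were 58 for Dyrk1, 932 for HDAC1, 1341 for Mef2c, 96 for HDAC1 against HDAC2 and 246 for Mef2c against Mef2d. Without the 3 B-rich libraries Mef2c had 1307 and Mef2d 1467, while Dyrk1, with a library fewer too, had 2411; the cause was not tested. With length and GC trends removed HDAC1 had 1011 and the Mef2d gene in its own label 0.24; the cause was not tested. Dyrk1a, at 0.25, lost its call at 0.25 with no filter, 0.23 with RLE, 0.26 without the B-rich libraries, 0.10 with trends removed and 0.25 in its 2 groups alone; the cause was not tested. With 1 library left out, counts ran from 1186 to 2595 for Dyrk1, 421 to 1721 for HDAC1, 1329 to 3284 for HDAC2, 1150 to 2428 for Mef2c, 1079 to 2814 for Mef2d, 54 to 210 for HDAC1 against HDAC2, 240 to 365 for Mef2c against Mef2d and 3563 to 5135 over 6 groups, and Dyrk1a from 0.19 to 0.30; the cause was not tested. Same-numbered libraries correlated at a median of -0.00422, but all 3 pairs exceeded 0.1 for wild type with HDAC2, HDAC1 with HDAC2 and Mef2c with Mef2d, where the replicate block gave 2867, 160 and 337 genes. That block gives each replicate number the same effect in all 6 groups. Some same-numbered libraries went opposite ways (HDAC2 and Mef2d replicate 2, r -0.453), so the block cannot fully account for these pairings. The DESeq2 test set beforehand as an alternative was not run because the deposited unit is FPKM, and recovered reads were tested with voom alone. At 15.9 to 24.1 M reads and 3 libraries, the smallest simulated fold was mostly missed (22% recovered), even among the well-read genes that the simulation changed.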

Other observations

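The gene family tests here were chosen only after the results were seen. Fisher tests count the genes of a family as independent, which genes regulated together or at a shared locus are not, so their p-values may be too small. They were not rerun with 1 library left out. Replication-dependent histone genes, transcribed in S phase, were lower with 3 labels, with 29 of 43 fallen for HDAC2, 22 for Mef2c and 27 for Mef2d (Fisher, adjusted over 98 tests, p 2.58e-18, 9.37e-15 and 5.52e-18; median log2 -0.86, -0.69 and -0.82). In the HDAC1-labelled libraries 3 fell (adjusted p 0.394) and with the Dyrk1 label 0. Hist1h4c, a histone H4 gene, was at 0.167 ± 0.144 FPKM with the Mef2c label and 6.12 ± 1.62 in wild type.

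T cell receptor alpha joining segments were higher than wild type with 4 labels, 23 of 58 for Dyrk1, 28 for HDAC1, 25 for HDAC2 and 24 for Mef2d (adjusted p 1.86e-07, 3.20e-12, 9.02e-06 and 2.57e-06), and 5 for Mef2c (adjusted p 1). Alpha variable segments instead differed with the Mef2c label, where 23 of 69 fell (adjusted p 7.40e-11) and 14 rose (adjusted p 0.306). Immunoglobulin heavy variable segments rose at 44 of 90 with the HDAC2 label (adjusted p 5.85e-12) and 12 with the HDAC1 label (adjusted p 0.809). Of 8 TRIM genes at chromosome 7, 4 fell and 2 rose with the Mef2c label and with the Mef2d label. Fisher adjusted p-values for those falls were 0.00539 and 0.014.

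Some changes could be reads moved between near-identical copies, for which the sum over copies would stay level (under 0.2), a prediction made for Rps3a and Atp6v0c before the sums were computed and applied to other families after. In Mef2d-labelled libraries the ribosomal protein gene Rps3a1 was at a log2 ratio of -2.11 to wild type and its copies Rps3a2 and Rps3a3 at 5.13 and 9.02. Their sum was at -0.69 (SE 0.0459), not level as moved reads alone predict. Dyrk1-labelled libraries had the same pattern (-1.31, 4.45 and 8.29, sum -0.53, SE 0.110). Without the pattern the sum was still at -0.22, -0.25 and -0.17 in the HDAC1, HDAC2 and Mef2c labels. A sum can also fall where reads that match several copies go uncounted, which was not examined, so moved reads stayed undecided. In Mef2c-labelled libraries the proton pump gene Atp6v0c was at -1.45 and Atp6v0c-ps2 at 6.22, and the sum at -0.40 (SE 0.0698) left it undecided, with the same pattern in the HDAC2 (-0.85 and 5.39) and Mef2d (-0.80 and 5.48) labels. Tma7 fits moved reads, with the parent at -0.59 and -0.44, Tma7-ps at 4.76 and 4.32, and sums of -0.11 (SE 0.122) and -0.07 (SE 0.0517) in the Mef2c and Mef2d labels. Rps13 sums were at -0.63 and -0.58 in the Mef2c and Mef2d labels, not level. They were also at -0.35, -0.2 and -0.33 in the Dyrk1, HDAC1 and HDAC2 labels, where Rps13-ps1 did not rise, so moved reads stayed undecided. Rpl34 was undecided too, with sums of -0.43 (SE 0.0558) and -0.63 (SE 0.236) in the Mef2c and Mef2d labels.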
